A study of Homo sapiens with 6 samples.

How the data were processed

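The labels describe RNA from 6 PC-9 cell samples in 2 groups of 3. Per the labels' protocols, polyadenylated RNA was selected, ribosomal RNA was removed, and stranded libraries were sequenced on an Illumina instrument. The submitters' processing notes name Bowtie 0.12.2 and DESeq2 1.6.3, with a human build (GRCh37) and a mouse build, without giving the role of each. How reads were assigned to overlapping genes and the number of genes tested are not given in the sources used here.

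The values come from 8 tables, a higher and a lower list for each of 4 comparisons. Each row gives a gene, its locus, strand and class. Per the file headers, the authors deposited a log2 fold change, a fold change as a linear ratio, and a p-value with its q-value, called adjusted p here. The authors also deposited 2 group levels per gene under a header that reads FPKM. These are on a log2 scale, because their difference equals the log2 fold change in each listed row (largest deviation 0.0). Whether an offset was added before the log is not given in the sources used here. CST1 had a level of exactly 0.0 in HN, which a log2 with an offset of 1 gives for a value of 0. With such an offset, each printed fold is a ratio of levels with 1 added. It then understates the ratio without the offset, most of all for genes with low levels. In the tables used, the listed genes had an unadjusted p under 0.05, and the smallest fold in either direction was 1.50. They are lists of selected genes, so a gene that is not listed has no value here and cannot be read as unchanged.

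The group codes of the tables match no label of the 6 samples. The tables also hold 48 columns of single-library values under 12 distinct names, 3 per group code, which match no sample label either and were not used. The planned test of OE against Con, with its alternatives, was therefore not run, and OE and Con were not analysed here. Without counts, depth is unknown and gives no precision, and values are given without a replicate spread because the single-library columns were not used.

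Before the data were examined, 28 gene lists with 517 distinct genes were fixed. For each comparison, the higher and lower members of a list were set against the higher and lower numbers of the other listed genes in a two-sided Fisher's exact test. This was done where at least 3 members were listed, and the 16 tests were adjusted together by the Benjamini-Hochberg method. The result of 1 of these list tests is not reported here. The test compares directions among listed genes only and treats genes as independent. On simulated data made from HT vs HN (537 genes, 100 draws), a seeded list with 6 or 12 members, all lower, was called in 100.0% of draws. With 4 or 5 members it was called in 0% of draws, so a list that small was out of reach of the adjusted threshold there. Other lists were called in 0% of tests.

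Genes listed in 2 comparisons without a common group were compared by direction with Fisher's exact test. For HT vs HN and HT vs LT, which have HT in common, the chance overlap was simulated from 200000 unchanged genes with 3 normal values per group and a p threshold of 0.05. The simulation has no fold threshold and no pairing between groups.

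Named genes were chosen by a rule fixed before the data were examined. It took the 8 genes with the largest fold per direction with an adjusted p under 0.05, FOS and JUN where listed, and up to 3 members with the smallest p from each list with 3 or more listed members. It also took genes listed in 3 or 4 comparisons. The adjusted p part selected 0 genes. The genes with the largest folds named here, and list members beyond the 3 of the rule, were chosen after their values were seen.

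Settings fixed before the data were examined were an adjusted p under 0.01, an absolute log2 fold change of at least 2, 1 row per gene symbol, protein-coding genes only, and matching of older symbols. Of 1230 gene identifiers, 1221 matched the name table. A filter on the unadjusted p at 0.01 was added after the data were seen. The chromosome tests were also chosen after the data were seen. They used 19864 protein-coding genes of a GENCODE annotation of another build (GRCh38) for gene numbers, GC content and gene density, and none of its coordinates is printed. Random gene sets were drawn to match 10 bins each of GC content of the longest transcript and of the number of genes within 1 Mb. On simulated sets of 330 genes for HT vs HN, 4.0% of 100 unchanged sets and 100.0% of sets with 30 genes moved to 1 chromosome were called.

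Calculations were done in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.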

Results

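RNA sequencing was described for 6 samples of PC-9, a human lung adenocarcinoma cell line grown in culture. The labels name 2 groups of 3 samples, mock-transfected control cells (Con) and overexpressing cells (OE). The series text names FOS as the overexpressed gene, whereas the labels of the OE samples name a c-Jun plasmid, and both genes encode subunits of the AP-1 transcription factor. The values used here come from 8 tables of listed genes, which make up 4 comparisons between the group codes HT, HN, LT and LN. These codes match no label of the 6 samples and are not explained in the sources used here. The OE and Con samples were therefore not analysed here, and the codes are used only as names. The listed genes include markers of several cell types. On the log2 scale of the authors' deposited table, AGER stood at 8.37 and GZMA at 5.22 in LN, and CD68 at 7.05 in HN. These alveolar, T and NK cell and macrophage markers argue against reading the values as those of PC-9 cells alone. Whether the groups differed in their mix of cell types was not tested.

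The tables listed 1395 genes over the 4 comparisons, of which 1230 were distinct, and each listed gene was protein-coding. HT vs HN listed 336 genes as higher and 201 as lower in HT. LT vs LN listed 174 genes as higher and 275 as lower in LT. HT vs LT listed 137 as higher and 124 as lower in HT, and HN vs LN listed 76 as higher and 72 as lower in HN. The balance of higher and lower genes turned at an absolute log2 fold change of at least 2, which left 12 higher and 16 lower genes in HT vs HN, 10 and 2 in LT vs LN, 2 and 11 in HT vs LT, and 0 and 4 in HN vs LN. The p-values in the authors' deposited table were under 0.05 before adjustment, but the smallest adjusted p of any gene was 0.157, so 0 genes passed an adjusted p of 0.05. The gene differences below are therefore given as listed values and not as called changes. Read depth is unknown for these values, and the group levels carry no replicate error here.

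**Figure D1:**
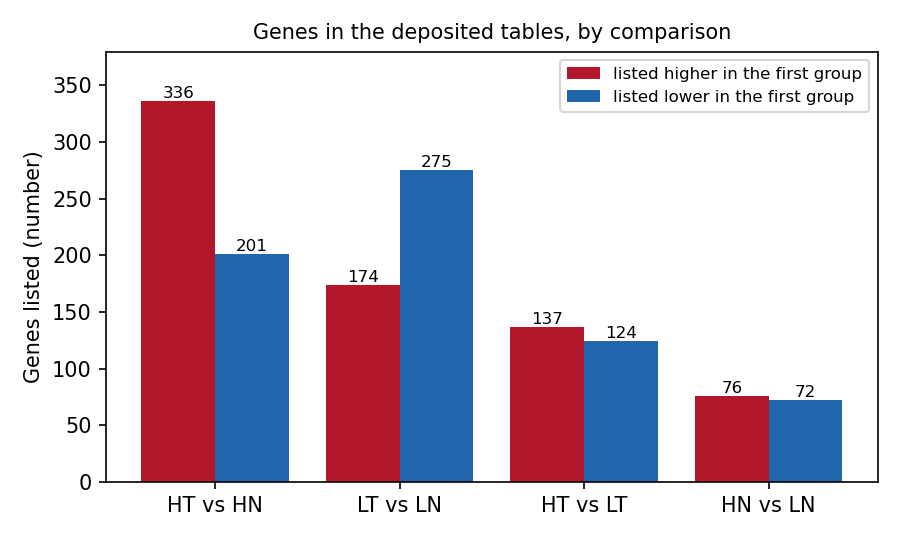
Number of genes (y axis) listed in the deposited tables as higher (red) or lower (blue) in the first group of each of the 4 comparisons (x axis). HT vs HN had more genes listed as higher (336) than lower (201), and LT vs LN more as lower (275) than higher (174), and both balances turned at an absolute log2 fold change of at least 2; no listed gene passed an adjusted p of 0.05.

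In HT vs HN, genes of the AP-1 family and other immediate early genes, which are transcribed within minutes of a stimulus, were listed mainly as lower in HT. FOS (ENSG00000170345.9_3, chromosome 14, 75745477 to 75748933, plus strand) had a log2 fold change of -1.80 and an adjusted p of 0.719 in the authors' deposited table. JUN (ENSG00000177606.6_2, chromosome 1, 59246460 to 59249999, minus strand) had a log2 fold change of -0.98 and an adjusted p of 0.725 in the authors' deposited table. FOSB, JUND and ATF3 stood at -2.31, -1.24 and -1.62 on the log2 scale in the authors' deposited table. The coordinates are those of whole genes as the tables give them, and GRCh37 is the human build in the submitters' processing notes.

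All 5 listed members of the AP-1 list were lower, 0 were higher, and the other 10 members were not listed. Against the direction of the other listed genes this gave p = 0.00712 in Fisher's exact test and an adjusted p of 0.114 over 16 list tests. Among immediate early genes, the authors' deposited table listed EGR1 (4.49-fold), ZFP36 (5.02-fold), NR4A1 (4.47-fold) and DUSP1 (3.18-fold) as lower. MYC, a growth-promoting transcription factor, was the exception and was listed as 3.18-fold higher in the authors' deposited table. This list of 4 lower members and 1 higher gave p = 0.0678 in Fisher's exact test (adjusted p = 0.181).

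Of the 21 genes of the inflammatory cytokine list, 4 were listed, all as lower in HT, and 17 were not listed. The authors' deposited table gave 5.75-fold lower CXCL2, 5.15-fold lower IL6, 4.0-fold lower CSF3 and 2.35-fold lower CCL2 in HT than in HN. These 4 genes gave p = 0.0193 in Fisher's exact test and an adjusted p of 0.122. The chemokine genes CXCL13 and CCL19, which are not on that list, were listed as higher in HT.

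Of the 21 genes of the T and NK cell list, 3 were listed, all as higher in HT, and 18 were not listed. FOXP3, the transcription factor of regulatory T cells, was 2.31-fold higher, PDCD1 1.74-fold higher and CD2 1.69-fold higher in the authors' deposited table. The HN levels of FOXP3 (0.31) and PDCD1 (0.64) were low on the log2 scale. The 3 listed members gave p = 0.296 in Fisher's exact test (adjusted p = 0.364). Matrix genes were split, with COL10A1 8.34-fold, COMP 2.65-fold and COL1A1 2.07-fold higher and DCN, a small proteoglycan, 3.49-fold lower in the authors' deposited table (p = 1.0, Fisher's exact test; adjusted p = 1.0). Among genes of the amino acid and unfolded protein stress response, PSAT1 was 4.29-fold, ASNS 1.75-fold and TRIB3 1.69-fold higher, and VLDLR, a lipoprotein receptor, had a log2 fold change of -0.68 in the authors' deposited table (p = 1.0, Fisher's exact test; adjusted p = 1.0).

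Because no gene met the adjusted p in the naming rule, the genes with the largest folds were chosen after their values were seen. CST1, a secreted cysteine protease inhibitor, was listed at 0 in HN and at 3.98 in HT on the log2 scale in the authors' deposited table. Higher in HT were also CXCL13 (8.53-fold), CRABP2 (7.96-fold), CCL19 (6.18-fold), MMP9 (5.29-fold) and HS6ST2 (4.78-fold) in the authors' deposited table. The read-through model NME1-NME2 was listed at 17.9-fold higher in the authors' deposited table, and it shares its sequence with NME2, so its reads depend on how they were assigned. Lower in HT were SOSTDC1 (7.70-fold), IGFBP6 (6.77-fold), PTGER4 (4.99-fold) and BCHE (4.93-fold) in the authors' deposited table.

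In LT vs LN, listed genes of the interferon response and of cytotoxic lymphocytes were lower in LT. Over all listed genes, 174 were higher and 275 lower, against 39 and 39 at an unadjusted p under 0.01, chosen after the data were seen, and 10 and 2 at an absolute log2 fold change of at least 2. IFIT3 was 2.35-fold, IDO1 2.15-fold, IFIT1 2.01-fold, IFIT2 1.99-fold, RSAD2 1.74-fold and IFI27 1.73-fold lower in LT in the authors' deposited table. All 6 listed interferon genes were lower, with p = 0.0862 in Fisher's exact test (adjusted p = 0.197). Lower genes were the more frequent in LT vs LN, so 6 members all lower could not give a smaller p. The other 17 of the 23 members of the interferon list were not listed. PRF1 and GZMB, which encode the pore-forming and protease components of cytotoxic granules, were 4.58-fold and 2.29-fold lower, and GZMA 2.0-fold lower in the authors' deposited table. These 3 T and NK cell markers gave p = 0.286 in Fisher's exact test (adjusted p = 0.364), and the other 18 members of that list were not listed.

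Alveolar epithelial markers were split in direction in LT vs LN. AGER, CAV1 and RTKN2, known from flat type I alveolar cells, were 3.61-fold, 3.06-fold and 3.84-fold lower in the authors' deposited table. HOPX, also known from type I cells, was 2.61-fold higher in the authors' deposited table. NAPSA and SLC34A2, known from surfactant-producing type II cells, were 1.89-fold and 2.0-fold higher in the authors' deposited table. With 3 members higher and 3 lower, Fisher's exact test gave p = 0.681 and an adjusted p of 0.778. Of the list of targets of NRF2, a regulator of antioxidant genes, 2 were listed, too few for a test: ABCC3 was 3.41-fold and NQO1 1.78-fold higher in the authors' deposited table.

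The genes with the largest folds in LT vs LN were likewise chosen after their values were seen. Higher in LT were MUC21 (8.38-fold), CRABP2 (7.73-fold), GDF15 (7.44-fold), CD1A (6.08-fold), ABCA4 (5.18-fold), VSTM2L (5.03-fold), SGPP2 (4.44-fold) and SFN (4.35-fold) in the authors' deposited table. Lower in LT were ITLN2 (5.60-fold), UPK3B (3.87-fold), ZBED2 (3.63-fold), GNG2 (3.30-fold) and SPOCK2 (3.08-fold) in the authors' deposited table.

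Genes listed in both HT vs HN and LT vs LN, which have no group code in common, mostly had the same direction. Of 52 such genes, 20 were higher in both comparisons and 31 lower in both, and 1 differed (p = 1.67e-13, two-sided Fisher's exact test of direction). CRABP2, a retinoic acid carrier, had log2 fold changes of 2.99 and 2.95, and HS6ST2, a heparan sulfate sulfotransferase, 2.26 and 1.95 in the authors' deposited table. BCHE stood at -2.30 and -1.27 and the homeobox gene HOXA5 at -2.06 and -1.50 in the authors' deposited table. The exception was ARRDC3, with -0.76 in HT vs HN and 1.03 in LT vs LN in the authors' deposited table. With an unadjusted p under 0.01, chosen after the data were seen, 3 shared genes were left (p = 1.0, Fisher's exact test). These were ENPP3, CLPTM1L and SLC35B2, each higher in both comparisons. With no lower gene left, the test could not give a smaller p, so it does not speak against the agreement. The p-value treats genes as independent, which genes expressed together are not.

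**Figure D2:**
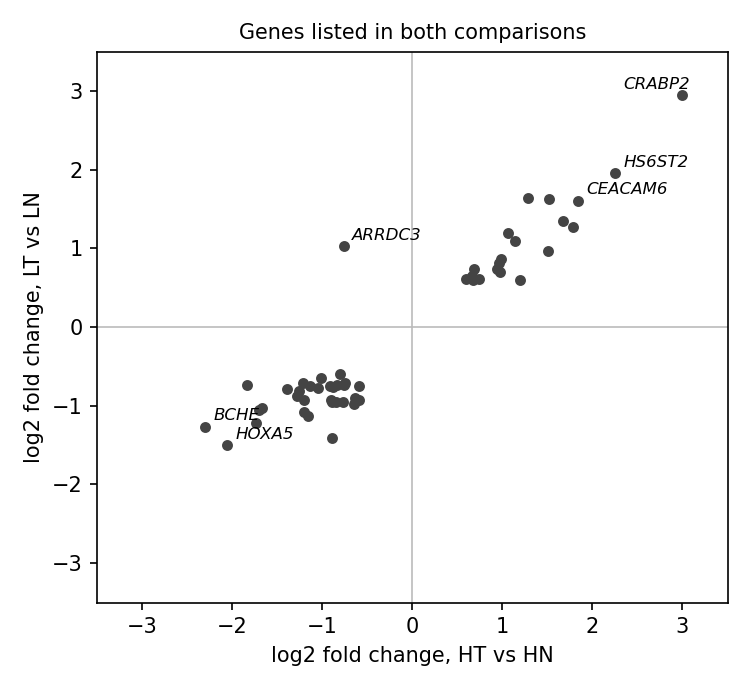
Each point is 1 of the 52 genes listed in both comparisons, with its log2 fold change in HT vs HN (x axis) and in LT vs LN (y axis) from the deposited tables; labels mark the 5 genes with the largest mean absolute values and ARRDC3. In all, 20 genes lie in the upper right, 31 in the lower left, and ARRDC3 alone in the upper left.

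In HT vs LT, AP-1 and other immediate early genes were again listed as lower in HT. FOS had a log2 fold change of -2.00 and JUN of -1.29, each with an adjusted p of 0.988 in the authors' deposited table. FOSB, ATF3 and JUND stood at -2.39, -1.48 and -0.96 in the authors' deposited table. All 5 listed AP-1 members were lower, with p = 0.0232 in Fisher's exact test and an adjusted p of 0.122. ZFP36 was 5.80-fold, EGR1 5.55-fold, DUSP1 3.88-fold, NR4A1 3.66-fold and BTG2 2.87-fold lower, and MYC 3.56-fold higher in the authors' deposited table. These 6 immediate early genes gave p = 0.105 in Fisher's exact test (adjusted p = 0.200).

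The 9 AP-1 and immediate early genes listed as lower in HT vs HN were all listed as lower in HT vs LT too. Both comparisons use the HT group, so chance values in HT enter both. With 3 values per group and no effect at all, simulated groups gave 16.2% of genes lower in one comparison that were also lower in the other. Over all genes, 25 of the 201 genes listed as lower in HT vs HN (12.4%) were also listed as lower in HT vs LT. The simulated genes were independent of each other, which genes expressed together are not. The 16.2% therefore gives no chance level for the 9 genes as a set. On the log2 scale of the authors' deposited table, the FOS level was 6.45 in HT, 8.25 in HN and 8.46 in LT.

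**Figure D3:**
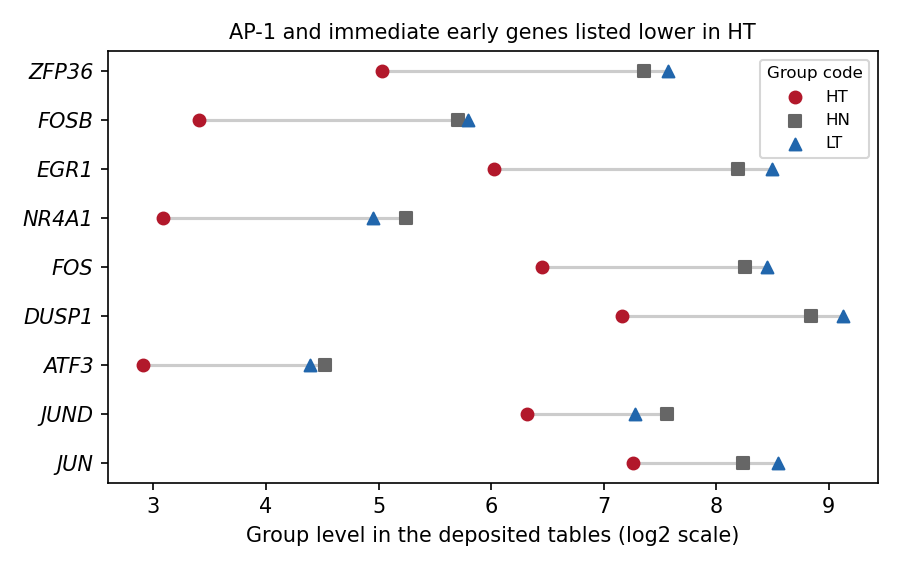
Group levels on the log2 scale (x axis) of the 9 AP-1 and immediate early genes (y axis) listed as lower in HT than in both HN and LT, from the deposited tables; circles are HT, squares HN and triangles LT, with 1 value per group and no error. The HT level is the lowest for each gene, for example 6.45 for FOS against 8.25 in HN and 8.46 in LT.

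Interferon response genes were listed as higher in HT than in LT. ISG15 was 3.18-fold, IFI6 2.52-fold, IFIT1 1.96-fold, OAS1 1.89-fold, RSAD2 1.76-fold and IRF7 1.62-fold higher in the authors' deposited table. All 6 listed members were higher, with p = 0.0306 in Fisher's exact test (adjusted p = 0.122), and 17 of the 23 members were not listed. LT vs LN, where interferon genes were lower in LT, also uses the LT group, so chance values in LT enter both. IFIT1 and RSAD2 were listed in both comparisons, and their HT level minus their LN level was -0.03 and 0.02 on the log2 scale. Of the cytokine list, CXCL2 was 7.16-fold, CSF3 2.22-fold, NFKBIA 1.98-fold and CCL4 1.92-fold lower in HT in the authors' deposited table. NFKBIA is on that list but is not itself a cytokine gene. These 4 genes gave p = 0.0497 in Fisher's exact test (adjusted p = 0.159).

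The largest folds in HT vs LT, again chosen after the values were seen, included 2 models of 1 locus. BLOC1S5-TXNDC5, a read-through model, was 45.5-fold lower and TXNDC5, which encodes a protein disulfide isomerase, 7.76-fold higher in the authors' deposited table. The models overlap on chromosome 6, from 7881755 to 8064597 and from 7881750 to 7911047, so their reads are not separable without the assignment rule. CST1 was 7.37-fold, CST2 3.39-fold, EFHD1 2.92-fold and GNAS 2.68-fold higher in HT in the authors' deposited table. SCGB3A1, a secretoglobin of airway secretory cells, was 13.0-fold lower, ROS1, a receptor tyrosine kinase, 7.20-fold lower and THBS1 4.97-fold lower in the authors' deposited table.

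In HN vs LN, the listed macrophage markers were higher and the listed T and NK cell markers lower in HN. Of the macrophage and monocyte list, 15 of 18 members were not listed, and of the T and NK cell list, 18 of 21. MARCO, a scavenger receptor of macrophages, was 2.78-fold, CD68 1.83-fold and the complement gene C1QA 1.63-fold higher in the authors' deposited table (p = 0.245, Fisher's exact test; adjusted p = 0.364). IL7R was 1.87-fold, KLRD1 1.79-fold and GZMB 1.77-fold lower in the authors' deposited table (p = 0.113, Fisher's exact test; adjusted p = 0.200). FTH1 and FTL, which encode the iron-storage protein ferritin, were 2.10-fold and 1.51-fold higher in the authors' deposited table. These were the 2 listed members of both the NRF2 target and the ferroptosis suppressor list, too few for a test.

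Of the genes with the largest folds in HN vs LN, chosen after the values were seen, LITAF was 3.53-fold, LASP1 2.68-fold and NBL1 2.51-fold higher in HN in the authors' deposited table. C10orf10 was 5.07-fold, GNG2 3.84-fold, MMP9 3.74-fold and SOX17, an endothelial transcription factor, 2.69-fold lower in the authors' deposited table. The 5 genes listed in both HT vs LT and HN vs LN had the same direction in each, 3 higher and 2 lower. Fisher's exact test gave p = 0.10, the smallest that 3 genes against 2 allow.

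The number of comparisons that listed a gene reached 3 for SLC35B2, ARRDC3 and NBL1. SLC35B2, a Golgi transporter of the sulfate donor PAPS, was 2.29-fold higher in HT than in HN, 1.52-fold higher in LT than in LN and 1.76-fold higher in HT than in LT in the authors' deposited table. NBL1, a secreted antagonist of BMP signalling, was 3.56-fold lower in HT than in HN and 1.67-fold lower in LT than in LN in the authors' deposited table. ARRDC3, an arrestin-domain gene, was 3.06-fold lower in HT than in LT in the authors' deposited table.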

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

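The filter on the unadjusted p was chosen after the data were seen; the other settings were planned. No listed gene had an adjusted p under 0.01, so that planned filter left 0 genes and gave no further value. An unadjusted p under 0.01 left 81 higher and 27 lower genes in HT vs HN, 39 and 39 in LT vs LN, 21 and 34 in HT vs LT, and 22 and 21 in HN vs LN. An absolute log2 fold change of at least 2 left 12 and 16, 10 and 2, 2 and 11, and 0 and 4 genes in the same order. The stricter fold turned the balance of higher and lower genes in each comparison, and the unadjusted p turned it in HT vs LT and evened it in LT vs LN. Both filters can only remove genes, which is the cause of the lower counts. With 1 row per gene symbol or protein-coding genes only, the 8 counts were unchanged. Neither setting removed a gene, so they tested nothing here. Matching older symbols left the 16 list tests on the same side of the threshold. No list kept 3 listed members at the unadjusted p under 0.01, and at the stricter fold 2 lists of HT vs HN did, with their direction kept. The 52 shared genes of HT vs HN and LT vs LN came down to 3 at the unadjusted p under 0.01 (p = 1.0, Fisher's exact test), where so few genes cannot pass. The stricter fold left too few shared genes for a test, as did both filters for HT vs LT and HN vs LN. No paired analysis was possible because no column could be matched to the OE and Con samples, and the single-library columns, which match no sample label, were not used. Unknown depth leaves the precision of low levels open.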

Other observations

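All tests in this part were chosen after the results were seen. Metallothionein genes, which bind zinc and copper, were listed as lower in HN than in LN. In the authors' deposited table MT1X was 5.51-fold, MT1M 5.11-fold, MT2A 2.65-fold and MT1E 2.48-fold lower, each with an adjusted p of 0.981. All 4 listed members were lower (p = 0.0536, Fisher's exact test, unadjusted). In HT vs HN, MT1M was 2.91-fold lower in the authors' deposited table. PYCR1, an enzyme of proline synthesis, was 3.91-fold higher in HT than in HN in the authors' deposited table.

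Genes listed in both LT vs LN and HT vs LT had LT standing apart in most cases. Of 28 such genes, 20 were higher in LT than in LN and lower in HT than in LT, and 6 were the reverse. Together these are 26 of 28 genes (92.9%). Both comparisons use LT, and simulated groups with no effect at all gave 96.5% of the genes called in both, so the arrangement is no more frequent than the shared group gives by chance. ROS1 had a group level of 5.57 in LT, 4.17 in LN and 2.72 in HT on the log2 scale of the authors' deposited table.

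The lower AP-1 and immediate early genes in HT could come from handling, since such genes respond to handling of cells within minutes. If HT and LT had a handling difference in common against HN, LT would lie below HN by a good part of the HT deficit, whose median over the 9 genes was -1.80; the codes do not say which groups were handled alike. The LT level minus the HN level had a median of 0.20 and ranged from -0.29 to 0.31, which argues against that as the whole explanation. The 9 genes were chosen for being lower in HT, and all 9 of HT vs HN also met the listing in HT vs LT. Handling of the HT material alone stays open: 0 of 12 heat-shock genes were listed as lower in HT, but unlisted genes have no value, and no biological explanation was tested because the labels do not define the groups.

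The opposite values of TXNDC5 and BLOC1S5-TXNDC5 in HT vs LT may reflect reads divided differently between overlapping gene models. Summed on the linear scale with an offset of 1 removed, both models together differed by -0.62 on the log2 scale, and by -0.60 with no offset. Each model alone differed by 2.96 and -5.51 in the authors' deposited table. Under their FPKM header the levels are scaled by gene length, and the lengths of both models were not accounted for. A division of reads need not keep such a sum, so the sum cannot decide. A shift in transcript use at the locus could give the same values, so both explanations stay open.

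Genes listed as higher in HT than in HN were gathered on chromosomes 6 (46 of 336, adjusted p = 7.28e-07, binomial test over 184 tests), 8 (27, adjusted p = 0.00269) and 20 (22, adjusted p = 0.00644). In 10000 random sets of protein-coding genes matched on GC content and gene density, an excess on any chromosome as large as on chromosome 6 (z = 7.07), 8 (z = 5.02) or 20 (z = 4.12) gave permutation p = 0.0001, 0.0001 (the smallest they can give) and 0.0024, which argues against chance placement, although the sets did not account for which genes are expressed. With 1 gene kept of each overlapping group, z was 6.93, 5.06 and 4.18, which argues against overlapping gene models as the whole explanation. A regional gain in the HT material is a hypothesis that stays open: higher against lower genes gave an adjusted Fisher's exact p over 92 tests of 0.0184, 0.159 and 0.424 for chromosomes 6, 8 and 20 in HT vs HN, and of 0.358, 0.546 and 0.0184 in HT vs LT, which has HT in common. Those tests take whole chromosomes. In windows of 10 Mb, higher genes of HT vs HN were most numerous on chromosomes 6, 8 and 20. Chromosome 6 held 19 from 30524663 to 39197226 and 14 from 40994650 to 49529620. Chromosome 8 held 16 from 141667999 to 146072894, and chromosome 20 held 11 from 60697517 to 62601218. A window on chromosome 1 held 10. In HT vs LT, windows on chromosomes 6 (10 higher genes) and 8 (7) held the most. No window was tested against gene density. Neighbouring genes are not independent, and whether a single library carries the excess was not tested.

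Other chromosomes went the opposite way in HT vs HN. Chromosome 12 held 6 higher and 18 lower genes (adjusted Fisher's exact p = 0.0145 over the 92 tests), and chromosomes 13 and 18 each held 0 higher and 6 lower (adjusted p = 0.0483 for each). In the matched sets, the lower genes of HT vs HN had their largest excess on chromosome 12 (z = 2.60), with a permutation p of 0.155 (adjusted p = 0.248). Higher genes had a median GC content of 54.5% and 30 genes within 1 Mb, against 49.8% and 18 for lower genes. Fisher's exact test did not account for this difference. Higher genes were below their expected share on chromosome 12 (6 of 336, adjusted p = 0.0416) and chromosome 2 (6 of 336, adjusted p = 0.00618) in the 184 binomial tests. Chromosome 2 did not go the opposite way, because lower genes were few there too (4 of 201). The ratio to the expected share was 0.285 for higher and 0.318 for lower genes. In the same binomial tests, genes listed as lower in LT than in LN were in excess on chromosome 7 (27 of 275) and chromosome 10 (23 of 275), each with an adjusted p of 0.00644. For these lower genes the largest excess on any chromosome had a permutation p of 0.0348 in the matched sets, or 0.0928 adjusted over the lists of the 4 comparisons. Genes listed as higher in HT than in LT were in excess on chromosome 6 (21 of 137, adjusted p = 0.000644) and chromosome 20 (15 of 137, adjusted p = 0.000547). On chromosome 8 the excess did not pass there (10 of 137, adjusted p = 0.211, and a permutation p of 0.109 in the matched sets).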
